A study of Homo sapiens with 12 samples.

How the data were processed

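Labelled RNA of HCT116 cells was measured in 12 libraries, 2 for each of 6 groups: DMSO, OTS964 and pladienolide B, each after the 4SU pulse and after the chase. The authors deposited 1 table of raw read counts per Ensembl gene ID with a column per library, and the column names match the sample titles by treatment, time and replicate number. BWA, featureCounts, Subread 1.4.6-p3 and the genome build GRCh38 are named in the submitters' processing notes, with no role or order. Whether reads were counted over exons or whole genes, the annotation, the strand setting and the handling of reads with several matches are not given in the sources used here. Reads of overlapping, antisense or near-identical genes can therefore not be told apart, and unspliced and spliced RNA are not separated. Labels speak of 4SU at 500 nM.

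The table held 60683 IDs, of which 17859 had no count in any library. It had no unnamed lines and no repeated IDs. Library totals ranged from 23173298 to 69072635 counts, so that 3 counts, taken as the floor, equal 0.0434 to 0.129 CPM. Intervals and floors cover counting error only. The table pairs 0 of the IDs with a symbol, and the reference table used here lists 0 genes with an Ensembl ID. For this reason 28 gene lists, classes of gene span and intron number, shares of mitochondrial and ribosomal RNA, and scaling to mitochondrial mRNAs, all planned before the data were examined, were not analysed here.

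Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. IDs were kept with filterByExpr by group, which left 24430, holding over 99.9% of the counts of each library. Libraries were scaled by TMM, whose mean factors were 1.47 in the DMSO pulse, 1.32 in the OTS964 pulse, 1.22 in the pladienolide B pulse, 1.22 in the DMSO chase, 0.612 in the OTS964 chase and 0.567 in the pladienolide B chase. TMM assumes that most IDs do not change, and the sources used here name no spike-in RNA against which that could be set. A quasi-likelihood model with the 6 groups as a cell-means design was fitted to all 12 libraries, which leaves 6 residual degrees of freedom, and the common biological coefficient of variation was 0.173. Each comparison was a two-sided contrast of this model, with Benjamini-Hochberg adjustment over the tested IDs and a threshold of 0.05. Standard errors are the log2 fold change divided by the square root of the F statistic. CPM values given for IDs are TMM-scaled, unless stated to be by library total, with their mean and SD over 2 libraries. Where a group held 1 to 3 counts of an ID, the ratio of summed counts, each divided by the summed TMM-scaled library sizes, is given with its exact 95% Poisson interval. IDs were grouped in 4 classes of equal size by mean CPM over all libraries. The libraries compared are part of this mean, so a rise or fall itself shifts an ID towards a higher or lower class.

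The rule for named items was fixed before the data were examined: the largest rises and falls in log2 fold change among IDs past the threshold, with a mean of at least 5 CPM over the libraries compared and both libraries of a group above both of the other. The rule asked for genes with a symbol. As none could be paired, it was applied to IDs, and 2 IDs are given per direction in each of the 7 planned comparisons of 2 groups. IDs named in the closing section outside this rule were chosen after their values were seen.

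The procedure was tested on simulated data in which 200 IDs were changed by known amounts, all with a DMSO mean of at least 1 CPM. IDs below that level were not tried. All other IDs were simulated without change, so the assumption of TMM held by construction. The test therefore cannot show how the procedure fares where many IDs change or the balance depends on the scaling. For OTS964 against DMSO in the pulse, over 22834 IDs, 10.4% of IDs changed 1.5-fold, 44.8% of those changed 2-fold and 87.9% of those changed 4-fold were called, with 8 false calls of 103. For the same comparison in the chase, over 21038 IDs, the shares were 7.46%, 58.2% and 90.9%, with 12 false calls of 116. For the similarity of the inhibitors, all 12 libraries were simulated 20 times from the DMSO means of their phase with no inhibitor effect. The 24430 IDs were drawn independently, so changes common to many IDs in a library are not part of these simulations. A shared covariance of 0.252 put into simulated data was recovered as 0.250 in the pulse and 0.255 in the chase.

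Replicates of a group differed by more than sampling noise in all 6 groups, with chi-square values of 14.3 to 165 per degree of freedom, and were kept as separate samples. The groups share replicate numbers, but the labels do not tie a number to a shared culture or day, and the analysis reported has no replicate block. Other settings, listed before the data were examined, were RLE size factors, library totals alone, upper quartile scaling, DESeq2 1.42.0, no filter, a filter at a mean of 5 CPM, fits on the libraries of a comparison alone, a replicate block, omission of each library in turn, and stricter thresholds. Library totals without the 10 most abundant IDs and counts thinned to the lowest total were added after the data were examined. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.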

Results

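Newly made RNA was measured by 4SU-seq in HCT116 cells, an established human colorectal cancer line. In this assay cells are given 4-thiouridine (4SU), a uridine analogue that enters RNA while it is transcribed, and the labelled RNA is biotinylated, captured and sequenced. Cells received DMSO as the solvent control, OTS964 at 50 nM, an inhibitor of the kinase CDK11, or pladienolide B at 186 nM, an inhibitor of the splicing factor SF3B1. DMSO and OTS964 were given 15 min before 4SU and pladienolide B 45 min before it, so that the inhibitors differed in both dose and time. Pladienolide B had no DMSO control of equal treatment time. Its comparisons with DMSO therefore cannot tell the inhibitor from the longer treatment. Labelling lasted 15 min. Pulse cells were lysed at once, and chase cells were returned to medium without 4SU and lysed 2 h later, per the treatment protocol. A separate label of the chase samples gives 15 min (DMSO, OTS964) or 45 min (pladienolide B) after labelling, equal to the time of treatment before 4SU. The names of the count columns give 2 h for the chase, like the protocol. The sources used here do not explain the other label.

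Each of the 6 groups held 2 libraries, 12 in all. Counts were given for 60683 Ensembl gene IDs, of which 24430 passed the filter on low counts and were tested. The pulse libraries held 23173298 to 26564845 counts each, the DMSO chase libraries 62635913 and 69072635, the OTS964 chase libraries 39004491 and 54655290, and the pladienolide B chase libraries 46858840 and 48391561. The mean number of IDs with at least 1 count was 32722 in the DMSO pulse, 32145.5 in the OTS964 pulse, 31088.5 in the pladienolide B pulse, 34007 in the DMSO chase, 30568.5 in the OTS964 chase and 30034 in the pladienolide B chase. The labels do not say that the libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Replicates correlated across tested IDs at r = 0.985 or above in 5 groups and at 0.972 in the OTS964 chase, on log2 CPM, the counts scaled by library size to those of a common total. OTS964 chase replicate 2 correlated more closely with the pladienolide B chase libraries, at 0.981 and 0.980, than with its own replicate. The files do not pair the gene IDs with names, so items are given by ID, and groups of IDs are defined by abundance and by direction of change.

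The most abundant IDs held a larger share of the counts in the inhibitor chase libraries than in the other libraries. The 10 IDs with most counts held 8.31% ± 0.587 (SD, n = 2) of the counts in the DMSO pulse and 8.56% ± 0.300 (SD, n = 2) in the DMSO chase. They held 12.5% ± 1.59 in the OTS964 pulse and 12.3% ± 1.01 in the pladienolide B pulse (SD, n = 2 each). In the chase the share was 33.6% ± 2.11 with OTS964 and 31.8% ± 0.793 with pladienolide B (SD, n = 2 each). The 100 IDs with most counts held 22.2% of the DMSO chase, 52.9% of the OTS964 chase and 53.1% of the pladienolide B chase. All 4 inhibitor chase libraries lay above both DMSO chase libraries, by 24.2 percentage points on average (exact permutation test, two-sided, p = 0.0667, n = 4 and 2, the smallest value that the 15 splits allow). For 2 libraries against 2 the smallest two-sided exact p is 0.333, so single inhibitors were not tested on this measure. IDs at 1 CPM or more, by library total, numbered a mean of 16826.5 in the DMSO chase, 15376.5 in the OTS964 chase and 15306.5 in the pladienolide B chase.

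**Figure D1:**
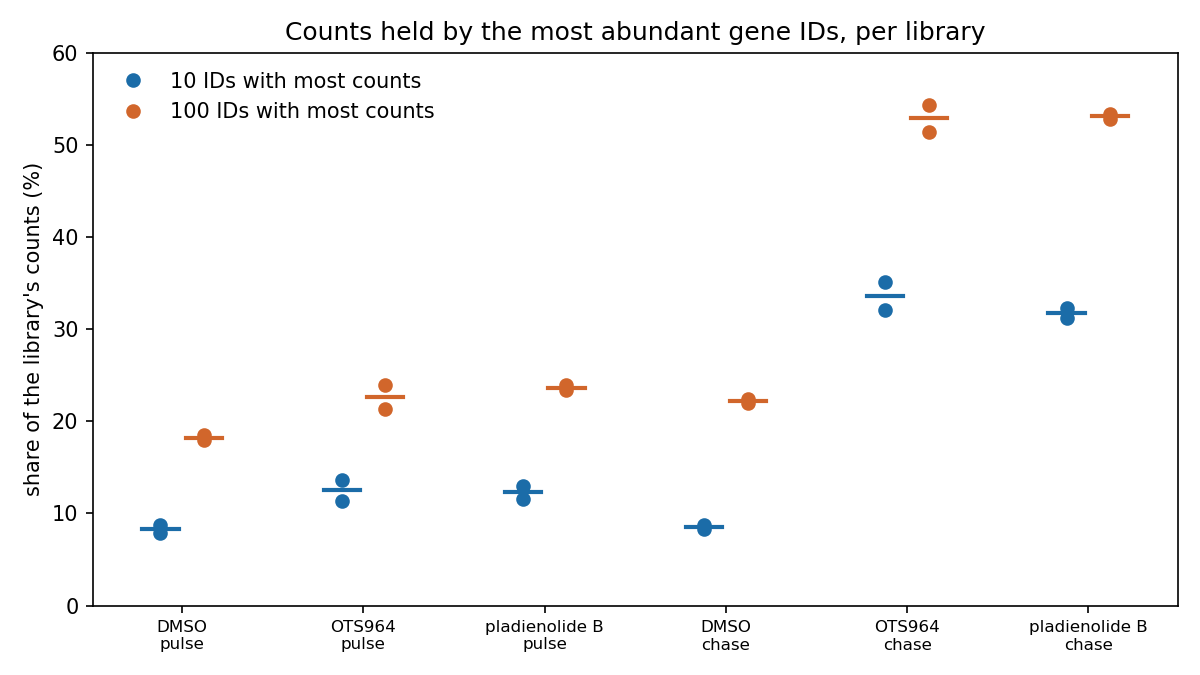
Share of each library's counts (%, y axis) held by its 10 and its 100 most abundant gene IDs, by group; each point is 1 library and each line the mean of 2. The OTS964 and pladienolide B chase groups have means of 33.6% and 31.8% for 10 IDs, against 8.56% in the DMSO chase.

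Which RNAs changed between labelling and the end of the chase in untreated cells was asked by comparing the DMSO chase with the DMSO pulse. Of the 24430 IDs, 6674 rose and 8853 fell (edgeR, adjusted p under 0.05), 3724 and 6155 of them by at least 2-fold. Falls prevailed among IDs of low abundance and rises among abundant ones. In the lowest of 4 classes of IDs by mean abundance 690 rose and 2717 fell, and in the highest class 2586 rose and 1566 fell. ENSG00000227081 rose from 0.170 and 2.05 CPM in the pulse libraries to 114 ± 48.1 CPM (SD, n = 2; log2 fold change 6.65, SE 0.75, adjusted p = 3.05e-05 in edgeR). ENSG00000234289 rose from 2 counts over both pulse libraries to 7256 over both chase libraries. After TMM scaling the ratio was 1663 with a counting interval of 460.1 to 13731, but the chase libraries differed (3.10 and 85.5 CPM). ENSG00000282164 fell from 12.4 ± 2.74 to 0.606 ± 0.271 CPM (SD, n = 2 each), and ENSG00000263142 from 39.8 and 10.1 CPM to 0.608 and 1.91 CPM. Leaving out 1 library moved the log2 fold change of 3 of these: from 6.65 to 5.84 or 9.40 for ENSG00000227081 (without DMSO pulse replicate 1 or 2), from 10.52 to 9.69 or 13.79 (pulse) and 11.48 or 6.68 (chase) for ENSG00000234289, and from -4.30 to -2.95 or -4.94 (pulse) and -3.67 or -5.34 (chase) for ENSG00000263142. With scaling to the library total alone 4965 IDs rose and 10776 fell (median log2 change -0.44), with totals without the 10 most abundant IDs 4950 and 10642, and with RLE size factors 7297 and 8190. A fit to these 4 libraries alone reversed the balance, with 8201 IDs risen and 8150 fallen.

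Whether inhibition of CDK11 changed RNA made within minutes was asked by comparing the OTS964 pulse with the DMSO pulse. In the pulse 652 IDs rose and 1049 fell (edgeR, adjusted p under 0.05), 6.96% of those tested. Falls were larger than rises. The median log2 change was 0.62 among IDs that rose and -1.23 among those that fell, and 134 rose but 704 fell by at least 2-fold. In the highest abundance class 374 IDs rose and 185 fell, while in the second class from the bottom 69 rose and 378 fell. ENSG00000178464 rose from 8.43 and 1.92 CPM in the DMSO libraries to 38.1 ± 5.88 CPM (SD, n = 2; log2 fold change 2.89, SE 0.48, adjusted p = 0.00984 in edgeR), and ENSG00000217094 from 1.48 ± 0.366 to 16.5 ± 8.56 CPM (SD, n = 2 each). ENSG00000267270 fell from 10.4 ± 0.377 to 1.48 ± 0.00888 CPM (SD, n = 2 each; log2 fold change -2.80, SE 0.34, adjusted p = 0.00427 in edgeR). ENSG00000263142 fell from 39.8 and 10.1 CPM in the DMSO libraries to 1.29 ± 0.00205 CPM (SD, n = 2). The number of calls depended on each library: it was 233 or 90 without DMSO pulse replicate 1 or 2, 49 or 4 without OTS964 pulse replicate 1 or 2, and 6026 (2872 rose, 3154 fell) in a fit to these 4 libraries alone, 3087 (1170 and 1917) without a filter and 2690 (1096 and 1594) in DESeq2. Each of the 4 named IDs missed the threshold when either OTS964 pulse library was left out, and ENSG00000217094 and ENSG00000263142 also without either DMSO pulse library. Without DMSO pulse replicate 1 or 2 the log2 fold change was 4.29 or 2.16 for ENSG00000178464 and -2.98 or -4.96 for ENSG00000263142, in place of -4.27, and without OTS964 pulse replicate 2 it was 2.82 for ENSG00000217094, in place of 3.47. With the library total alone 229 rose and 1863 fell, with upper quartile scaling 468 and 1333, and with totals without the 10 most abundant IDs 316 and 1379. A replicate block gave 3773 calls, with 1841 risen and 1932 fallen.

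The same question was asked of inhibition of SF3B1. With pladienolide B 3427 IDs rose and 4762 fell against DMSO in the pulse (edgeR, adjusted p under 0.05). Large changes were mostly falls. At least 2-fold falls numbered 3047 against 623 rises, and at least 4-fold falls 1252 against 184 rises. Direction followed abundance. In the lowest abundance class 216 IDs rose and 1270 fell, and in the highest 2052 rose and 586 fell. ENSG00000260672 rose from 0.956 ± 0.214 to 15.5 ± 0.269 CPM (SD, n = 2 each; log2 fold change 4.02, SE 0.45, adjusted p = 1.68e-04 in edgeR), and ENSG00000183298 from 1.88 ± 0.867 to 25.2 ± 10.7 CPM (SD, n = 2 each). ENSG00000286207 fell from 15.6 ± 3.33 to 0.533 ± 0.0765 CPM (SD, n = 2 each; log2 fold change -4.86, SE 0.33, adjusted p = 1.47e-05 in edgeR), and ENSG00000179841 from 22.1 ± 6.13 to 0.875 ± 0.470 CPM (SD, n = 2 each), where the log2 fold change of -4.66 went to -5.32 without pladienolide B pulse replicate 1. Without 1 of its libraries the comparison gave 3663 calls (without DMSO pulse replicate 1), 5204 (without DMSO pulse replicate 2), 4949 (without pladienolide B pulse replicate 1) or 4355 (without pladienolide B pulse replicate 2), and ENSG00000183298 missed the threshold in each of these. By the library total alone 1042 rose and 6641 fell and with totals without the 10 most abundant IDs 1392 and 5878, with ENSG00000183298 past the threshold in neither, while RLE size factors gave 4340 and 4292 and DESeq2 4446 and 3743.

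The fate of RNA labelled in the presence of OTS964 was followed by comparing the chase libraries. Against the DMSO chase 5794 IDs rose and 4101 fell with OTS964 (edgeR, adjusted p under 0.05), and 3680 rose and 1645 fell by at least 2-fold. In the lowest abundance class 909 IDs rose and 475 fell, in the second 1800 and 918, in the third 1261 and 1623, and in the highest 1824 and 1085. Falls thus prevailed in the third class alone. ENSG00000163046 rose from 9.78 ± 3.61 to 19488 ± 5418 CPM (SD, n = 2 each; log2 fold change 10.96, SE 0.47, adjusted p = 5.50e-07 in edgeR). In the 4 inhibitor chase libraries its counts stood at a ratio of 9.38 to 10.2 below those of ENSG00000227195, an ID chosen after its values were seen. ENSG00000251705 rose from 1 count over both DMSO chase libraries to 1340 over both OTS964 chase libraries. After TMM scaling the ratio was 3807 with a counting interval of 682 to 150478. The log2 fold change of this ID, 11.30, went to 10.54 or 12.71 without DMSO chase replicate 1 or 2. ENSG00000228331 fell from 55.9 ± 5.63 to 0.414 ± 0.142 CPM (SD, n = 2 each; log2 fold change -7.04, SE 1.27, adjusted p = 0.00136 in edgeR), and ENSG00000205670 from 14.1 ± 1.64 to 0.155 ± 0.0534 CPM (SD, n = 2 each). The balance of rises and falls rested on the scaling. Scaled to the library total alone 1372 IDs rose and 14909 fell, with a median log2 change of -0.93 over all tested IDs, and with totals without the 10 most abundant IDs 2673 rose and 9819 fell, with a median of -0.47. Rises and falls in this comparison, as in all others given here, are therefore relative to the bulk of IDs in the same library. They say nothing of amounts per cell. Fitted on its own 4 libraries, the comparison gave 5119 calls.

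With pladienolide B 6743 IDs rose and 5254 fell against DMSO after the chase (edgeR, adjusted p under 0.05), 4542 and 2587 of them by at least 2-fold. ENSG00000251705 again rose, from 1 count over both DMSO chase libraries to 1266 over both pladienolide B chase libraries. After TMM scaling the ratio was 3778 with a counting interval of 677 to 149322 (log2 fold change 11.29, and 10.52 or 12.70 without DMSO chase replicate 1 or 2). ENSG00000278591 rose from 2 counts to 1691, a TMM-scaled ratio of 2523 with a counting interval of 697 to 20849. However, 1.44 CPM of this ID stood in replicate 1 and 63.2 CPM in replicate 2. Its log2 fold change of 11.02 went to 10.16 or 13.16 without DMSO chase replicate 1 or 2 and to 11.97 or 6.51 without pladienolide B chase replicate 1 or 2. ENSG00000227081, which rose during the chase in DMSO, fell from 114 ± 48.1 to 0.315 ± 0.0121 CPM (SD, n = 2 each; log2 fold change -8.49, SE 0.89, adjusted p = 2.16e-05 in edgeR). ENSG00000228331 fell from 55.9 ± 5.63 to 0.0754 ± 0.0558 CPM (SD, n = 2 each), with a log2 fold change of -9.50 that went to -8.91 or -10.51 without pladienolide B chase replicate 1 or 2. Under the library total alone 2137 IDs rose and 15314 fell, with a median log2 change of -1.07, and with totals without the 10 most abundant IDs 3364 rose and 11716 fell, with a median of -0.65. In a fit on its own 4 libraries 6304 rose and 6448 fell.

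**Figure D2:**
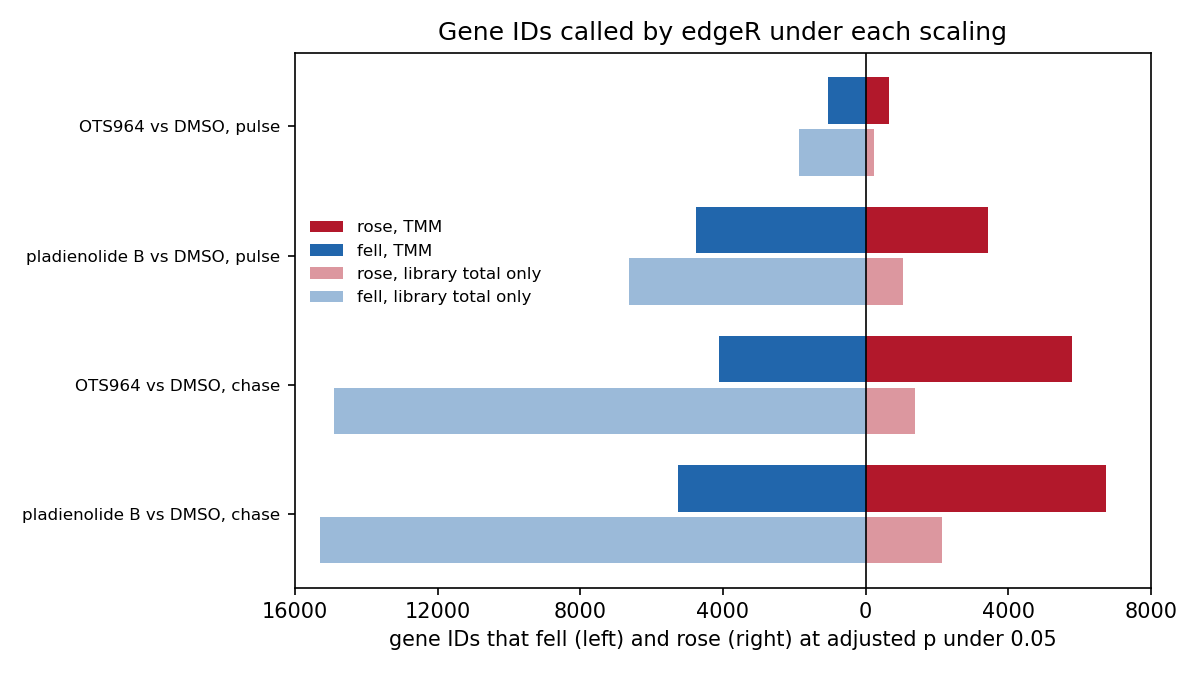
Number of gene IDs that fell (left of 0) and rose (right of 0) at adjusted p under 0.05 in edgeR, for each inhibitor against DMSO; dark bars use TMM scaling and pale bars the library total alone. In the chase, falls go from 4101 to 14909 with OTS964 and from 5254 to 15314 with pladienolide B.

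The effect of each inhibitor after the chase was set against its effect in the pulse with an interaction term. For OTS964 the effects differed for 6330 IDs, with 3648 higher and 2682 lower in the chase than in the pulse (edgeR, adjusted p under 0.05). For pladienolide B they differed for 8224 IDs, with 4929 higher and 3295 lower. The pulse and chase comparisons share no library. Of the 1049 IDs that fell with OTS964 in the pulse, 459 rose after the chase, where 249 would be shared by independent lists, and 196 fell, where 176 would. Of the 652 that rose in the pulse, 269 rose after the chase, against 155 for independent lists, and 94 fell, against 109. With pladienolide B, 1521 IDs rose in both and 1816 fell in both, against 946 and 1024 for independent lists, and 613 of the 4762 that fell in the pulse rose after the chase, against 1314, while 414 of the 3427 that rose in the pulse fell, against 737. The numbers for independent lists, here and below, take no account of abundance, with which calls varied in both lists. A small excess, such as 196 against 176, can therefore not be read as shared change. Across IDs, which are not independent replicates, the pulse and chase effects correlated at r = 0.0914 for OTS964 and at 0.384 for pladienolide B. ENSG00000178464, which rose with OTS964 in the pulse, had an effect lower in the chase by a log2 difference of -6.86 (SE 0.70, adjusted p = 1.94e-04 in edgeR). On the library total alone, 1614 IDs were higher and 10879 lower for OTS964, and 1976 and 9719 for pladienolide B. With totals without the 10 most abundant IDs the splits were 2281 to 6371 and 2913 to 6385. Upper quartile scaling gave 4348 to 1982 for OTS964 and a fit on its own libraries 2649 to 2997, and RLE size factors gave 4164 to 4253 and DESeq2 3975 to 4319 for pladienolide B. Leaving out DMSO pulse replicate 1, DMSO chase replicate 2, OTS964 pulse replicate 1 or OTS964 pulse replicate 2 gave 4024, 4161, 3822 or 3558 calls for OTS964.

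The change from pulse to chase within each inhibitor was compared with that in DMSO, a comparison added after the data were examined. With OTS964 6345 IDs rose and 7356 fell between pulse and chase, and with pladienolide B 6715 rose and 6098 fell (edgeR, adjusted p under 0.05). The changes shared much with DMSO. Of the 6674 IDs that rose in DMSO, 3669 rose with OTS964 and 265 fell, and 3432 rose with pladienolide B and 397 fell. Of the 8853 that fell in DMSO, 5462 fell with OTS964 and 438 rose, and 4177 fell with pladienolide B and 710 rose. Across IDs the change in DMSO correlated at r = 0.631 with that in OTS964 and at 0.577 with that in pladienolide B, with no library in common, and the changes with both inhibitors correlated at 0.757. Sizes depended on which treatment chose the IDs. IDs that rose in DMSO had a median log2 change of 1.09 in DMSO, 0.62 with OTS964 and 0.58 with pladienolide B, whereas IDs that rose with OTS964 had 0.74 in DMSO and 1.39 with OTS964. IDs that fell in DMSO had a median of -1.49 in DMSO and -0.97 with OTS964, and IDs that fell with OTS964 had -1.11 and -1.24. Library totals alone gave other splits: 2319 rose and 16683 fell with OTS964, and 2341 and 15420 with pladienolide B. With totals without the 10 most abundant IDs the splits were 3253 to 13610 and 3252 to 12434. For OTS964 rises outnumbered falls in DESeq2 (6419 to 6200), in a fit on its own libraries (5342 to 4836) and without OTS964 chase replicate 2 (5588 to 5544), and for pladienolide B falls outnumbered rises with RLE size factors (6301 to 6667), upper quartile scaling (6171 to 6941) and DESeq2 (6017 to 6268).

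The study asks about CDK11, SF3B1 and splicing, and the effects of OTS964 and pladienolide B were therefore compared with each other. After the chase most calls went the same way: 4798 IDs rose with both inhibitors and 3349 fell with both, while 16 rose with OTS964 and fell with pladienolide B and 9 did the reverse. Independent lists would share 1599 rises and 882 falls. Across IDs the effects correlated at r = 0.780. All libraries, DMSO included, were also simulated from the DMSO means with no inhibitor effect, each ID varying independently. These unchanged groups, set against shared simulated controls, gave 0.321 on average over 20 simulations. At most 1 ID rose with both groups and 1 fell with both. The covariance was 1.25 against 0.102 in the simulations, a difference of 1.15. In the pulse 564 IDs rose and 593 fell with both, against 91.5 and 204 for independent lists. The correlation was 0.565 against 0.476 simulated, and the covariance 0.471 against 0.107, a difference of 0.364. Both comparisons use the same 2 DMSO libraries, which were not split between the comparisons. The simulated groups share their controls too, but without changes common to many IDs in a library. Part of the excess may therefore come from such changes in the shared controls. Without OTS964 chase replicate 2 the correlation after the chase was 0.624.

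**Figure D3:**
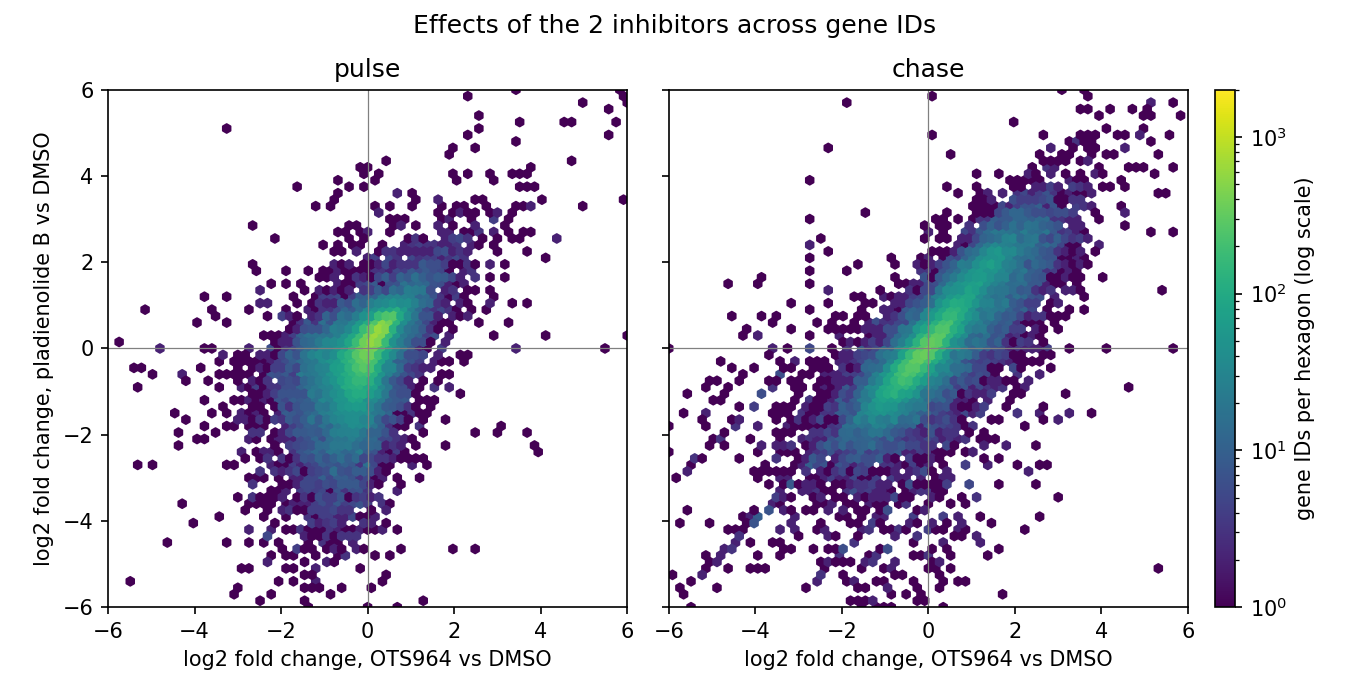
Log2 fold change against DMSO with OTS964 (x axis) and with pladienolide B (y axis) across 24430 gene IDs, in the pulse (left) and the chase (right); colour gives the number of IDs per hexagon on a log scale. The correlation is 0.565 in the pulse and 0.780 in the chase, and 86 and 89 IDs lie outside the plotted range of -6 to 6.

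Set directly against OTS964, pladienolide B gave 1168 IDs higher and 2660 lower in the pulse (edgeR, adjusted p under 0.05), and 1000 higher and 726 lower after the chase. In the pulse ENSG00000260672 was higher with pladienolide B, at 15.5 ± 0.269 against 1.09 ± 0.0170 CPM (SD, n = 2 each; log2 fold change 3.83, SE 0.45, adjusted p = 4.84e-04 in edgeR), and ENSG00000183298 at 25.2 ± 10.7 against 0.572 ± 0.244 CPM (SD, n = 2 each). ENSG00000269982 was lower, at 0.970 ± 0.106 against 13.8 ± 1.12 CPM (SD, n = 2 each), and so was ENSG00000270882, at 18.5 ± 8.70 against 923 ± 196 CPM (SD, n = 2 each). ENSG00000270882 missed the threshold without any 1 of the 4 libraries and with the filter at 5 CPM, and ENSG00000183298 without either OTS964 library or without pladienolide B replicate 2. After the chase ENSG00000249007 was higher with pladienolide B, at 12.9 ± 1.87 against 2.46 ± 0.209 CPM (SD, n = 2 each; log2 fold change 2.39, SE 0.30, adjusted p = 0.00241 in edgeR). ENSG00000278591 had 1691 counts with pladienolide B and 1 with OTS964, a TMM-scaled ratio of 1776 with a counting interval of 318 to 70190. However, its log2 fold change of 10.60 went to 11.58 or 6.12 without pladienolide B replicate 1 or 2. Without OTS964 replicate 1 or 2 it went to 9.85 or 13.33. This ID missed the threshold without pladienolide B replicate 2 or OTS964 replicate 1. ENSG00000196205 was lower, at 330 ± 137 against 3229 ± 791 CPM (SD, n = 2 each; log2 fold change -3.29, SE 0.33, adjusted p = 9.01e-04 in edgeR), and ENSG00000258427 at 1.28 ± 0.136 against 8.91 ± 4.33 CPM (SD, n = 2 each), where the log2 fold change of -2.79 went to -2.19 without OTS964 replicate 1. The doses and treatment times differed, so these values set the inhibitors side by side as used. In the pulse RLE size factors gave 1964 higher and 2144 lower and DESeq2 2517 and 1987, and leaving out OTS964 replicate 1, OTS964 replicate 2, pladienolide B replicate 1 or pladienolide B replicate 2 gave 1040, 1400, 2148 or 952 calls and the fit on its own 4 libraries 5993. After the chase the same omissions gave 814, 5781, 891 or 194 calls, with 82 higher and 112 lower in the last, while no filter gave 3293 and DESeq2 2660. The fit on its own 4 libraries gave 1 higher and 7 lower, with ENSG00000278591, ENSG00000196205 and ENSG00000258427 no longer past the threshold. The library total alone gave 773 and 805, and totals without the 10 most abundant IDs 681 and 802. A replicate block gave 3520 calls after the chase, with 2063 higher and 1457 lower.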

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

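The interaction tests were planned, and the tests of explanations in this part were chosen only after the values were seen. The effect of an inhibitor differed between pulse and chase by the interaction term for 6330 IDs with OTS964 and for 8224 with pladienolide B. Of the IDs named above for an inhibitor against DMSO, only those whose difference passed adjusted p under 0.05 in edgeR are given here. ENSG00000163046 had an OTS964 effect higher in the chase by 10.50 and ENSG00000267270 by 2.81 on the log2 scale. ENSG00000217094 and ENSG00000178464 had differences of -5.42 and -6.86. With pladienolide B the difference was 3.80 for ENSG00000286207 and -11.07 for ENSG00000227081. Others did not pass, such as ENSG00000228331 with either inhibitor and ENSG00000260672 with pladienolide B. All were named for large effects in the pulse or the chase, so the choice itself favoured a difference between them.

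The median ID took a lower share of the counts in the inhibitor chase libraries than in the DMSO chase, by a log2 difference of -0.997 over both inhibitors and all pairs of libraries. The 10 IDs with most counts in each library do not account for all of it: without them the median was -0.48 for OTS964 (-0.71 to -0.26 over 4 pairs of libraries) and -0.63 for pladienolide B (-0.79 to -0.48). Without the 100 IDs with most counts it was -0.21 and -0.33. Leaving IDs out of the total raises this median by an amount set by their shares of the counts, given above. These values therefore restate those shares and cannot show what lies behind the shift. A lower amount of labelled RNA from most genes cannot be told apart from a larger amount from the abundant ones, because the table holds no reference amount. The biological difference named by the design, treatment with either inhibitor, stays open.

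ENSG00000227195, chosen after its values were seen, held 15.6% (exact binomial 95% interval 15.59 to 15.61) and 8.37% (8.37 to 8.38) of the counts in the OTS964 chase libraries and 8.87% (8.87 to 8.88) and 7.88% (7.87 to 7.88) in those of pladienolide B, against 0.0518% (0.0512 to 0.0524) and 0.0356% (0.0351 to 0.0360) in the DMSO chase. In replicate 1 of the DMSO and OTS964 pulse it held 1.25% (1.24 to 1.25) and 0.860% (0.856 to 0.863), against 0.115% (0.114 to 0.117) and 0.132% (0.131 to 0.134) in replicate 2. With CPM taken by library total, carry-over of an inhibitor chase library would put ENSG00000163046 at 1187 and 777 CPM there. It stood instead at 21.4 and 26.5 CPM, at most 3.41% of that level. In the 4 inhibitor chase libraries the ratio of both IDs varied by only 1.09-fold (9.38 to 10.2) while ENSG00000227195 itself varied by 1.98-fold, and of 7 other IDs that rose at least 32-fold with both inhibitors and had 100 counts in each library, ENSG00000163046 was the only one with a ratio within 1.2-fold. Most of the 1.98-fold range came from OTS964 chase replicate 1, at 15.6% of the counts against 7.88% to 8.87% in the others. The steadiness of the ratio thus rests largely on 1 library. One RNA source counted under both IDs may lie behind the rise, but not behind the pulse values, where the ratio was 581 and 325. Parallel change of separate RNAs stays open.

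The OTS964 chase libraries differed more than other replicates, with an SD of log2 differences across IDs of 0.803 against at most 0.595 in the other groups. Unequal depth leaves the gap in place, at 0.828 against at most 0.646 with all libraries thinned to 23173298 counts. Replicate 2 correlated across IDs at 0.981 and 0.980 with the pladienolide B chase libraries and at 0.972 with its own replicate, but a label wrongly put on a pladienolide B library is argued against by IDs at least 2-fold apart between replicate 1 and 1 pladienolide B chase library, in the direction opposite to a shorter chase. Replicate 2 lay nearer to replicate 1 in 60 of 80 such IDs (75%) and 31 of 45 (68.9%). The pladienolide B library not used for the 2-fold limit did so in 9 and 2. At a 4-fold limit, tried before, the numbers were 3 and 2 of 4 against 1 and 1, too few to decide. Both pladienolide B chase libraries entered the fit that set the direction, so the choice of IDs was not fully independent of that library. The difference of replicate 1 minus replicate 2 correlated at -0.49 across IDs with the change from pulse to chase with pladienolide B, which shares no library, so replicate 1 may lie less far along that change, for reasons that stay open.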

How the results depend on the processing

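Thinned counts and totals without the 10 most abundant IDs were chosen after the data were examined, as were the comparisons of chase with pulse within an inhibitor. Of 108 alternative counts of calls for the 9 planned comparisons, apart from omitted libraries, 75 lay within 1.5 times the reported count and 33 did not. The balance of rises and falls turned over in 19 of the 108, in 8 of the comparisons, as given with each. Of 384 alternatives for the IDs named by the rule, 353 kept direction and call and 31 kept the direction but missed the threshold. Settings that dropped an ID from testing are not counted here, such as the filter at 5 CPM for ENSG00000267270 and ENSG00000251705. Leaving out 1 library moved the fold change by over 1.5 times in 13 of the 28 results for these IDs. Scaling to mitochondrial mRNAs, protein-coding genes only, totals without mitochondrial, ribosomal and RNA polymerase III genes, gene lists and gene structure classes were not run, since IDs could not be paired with names.

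Stricter settings lowered counts by construction. With at least 2-fold change, OTS964 gave 838 calls in the pulse and 5325 in the chase, pladienolide B 3670 and 7129, the DMSO chase against its pulse 9879, pladienolide B against OTS964 2160 in the pulse and 687 in the chase, and chase against pulse 8518 with OTS964 and 7601 with pladienolide B. At adjusted p under 0.01, OTS964 gave 188 and 5859, pladienolide B 4193 in the pulse, pladienolide B against OTS964 1441 and 436, and the interactions 2985 (OTS964) and 4544 (pladienolide B). With 12640 IDs tested, at a mean of 5 CPM or more, the counts were 6194 for OTS964 in the chase, 4706 and 7477 for pladienolide B, 8761 for the DMSO chase against its pulse, 2135 for pladienolide B against OTS964 in the pulse, 4178 and 5415 for the interactions, and 8142 and 8204 for chase against pulse with OTS964 and pladienolide B. At 10 counts or more in place of 1, the mean number of IDs was 22323 and 23208 in the DMSO pulse and chase, 21469.5 and 20235.5 with OTS964, and 20585.5 and 20051.5 with pladienolide B.

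For the other changes the cause was not tested. Without a filter, OTS964 gave 3087 calls in the pulse and pladienolide B against OTS964 3293 in the chase, and the correlation of both inhibitors in the chase was 0.607. DESeq2 gave 2690 and 2660 for the same comparisons. The library total alone gave 16281 for OTS964 in the chase and 12493 for its interaction. Fits on the libraries of a comparison alone gave 6026 and 5119 for OTS964 in pulse and chase, and 5993 and 8 for pladienolide B against OTS964. With a replicate block, OTS964 gave 3773 calls in the pulse, 1841 risen and 1932 fallen, and pladienolide B against OTS964 3520 in the chase, 2063 higher and 1457 lower, and the other planned counts stayed within 1.5 times. Deviations of same-numbered libraries correlated at -0.0398 to 0.294 over 15 pairs of groups, above 0 in 14 and above 0.1 in 6. As not every pair lay above 0.1, the numbers were not taken to pair the libraries, though the positive values leave a pairing possible.

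Leaving out each library in turn left a group with 1 library, assumed to vary like the other groups, and gave 4 to 233 calls for OTS964 in the pulse, 3663 to 5204 for pladienolide B in the pulse, 952 to 2148 and 194 to 5781 for pladienolide B against OTS964 in pulse and chase, and 3558 to 7506 for the OTS964 interaction. The correlation of the inhibitors in the chase ranged from 0.624 to 0.789. For the other planned comparisons the count stayed within 1.5 times: 6660 to 9579 for OTS964 and 8703 to 9774 for pladienolide B in the chase, 11740 to 14120 for the DMSO chase against its pulse, and 5756 to 6960 for the pladienolide B interaction. At these depths about 44.8% of 2-fold changes were recovered in simulated data for OTS964 in the pulse, among IDs with a DMSO mean of at least 1 CPM. Less abundant IDs were not tried, and a missing call is no sign of an absent change.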

Other observations

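The values in this part were looked up after the data were examined, and no explanation was tested for them. A set of 23 IDs rose at least 32-fold with both inhibitors in the chase (edgeR, adjusted p under 0.05), and 13 of them also rose at least 32-fold against the pulse of each inhibitor. Together they held 17.2% and 9.29% of the counts in the OTS964 chase libraries and 9.81% and 8.73% in those of pladienolide B, against 0.0539% and 0.0368% in the DMSO chase. Most of that was ENSG00000227195. Of the IDs among the 10 most abundant, 6 were so in all 12 libraries, and these held 5.30% and 5.91% of the DMSO pulse libraries, 7.12% and 6.54% of the DMSO chase, 15.7% and 20.8% of the OTS964 chase, and 20.5% and 20.7% of the pladienolide B chase.

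The first principal component of log2 CPM held 57.6% of the variance and the second 16.3%. On the first component the DMSO pulse libraries stood at -121 and -104 and the OTS964 pulse libraries at -115 and -108, while the pladienolide B pulse libraries lay nearer to the chase, at -54.0 and -33.7. The DMSO chase libraries stood at 29.4 and 62.5, with OTS964 chase replicate 1 between them at 55.4, while OTS964 chase replicate 2 stood at 122 and the pladienolide B chase libraries at 127 and 141. On the second component the DMSO chase libraries stood apart, at 102 and 115. OTS964 chase replicates 1 and 2 stood there at -33.9 and -13.1, and the pladienolide B chase libraries at -34.5 and -47.6.

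Some IDs were near 0 in 1 library of a group and abundant in the other. IDs with at most 3 counts in 1 library and at least 100 in the other numbered 7 in the DMSO pulse, 17 in the DMSO chase, 8 and 12 in the OTS964 pulse and chase, and 4 and 13 in the pladienolide B pulse and chase. ENSG00000264063 had 201058 counts in DMSO pulse replicate 1, 230784 in DMSO chase replicate 1, 437643 in OTS964 chase replicate 2 and 336371 in pladienolide B chase replicate 2, and 0 in the other 8 libraries. ENSG00000264462 was counted in the same 4 libraries alone, with 23373, 16453, 63639 and 42959 counts.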
